A study of Mus musculus with 14 samples.

How the data were processed

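Whole-brain RNA of mice lacking tenascin-R (Tnr) and of wild-type mice was measured on 14 single-colour oligonucleotide arrays, 1 array per sample. The labels name 4 groups: wild type at postnatal day 7 (P7, n = 4), knockout at P7 (n = 4), wild type adult (n = 3) and knockout adult (n = 3). Per the labels, total RNA was extracted from entire brains of male mice and the adults were 2 to 3 months old. The labels do not state whether each array came from a separate animal, so p-values measure only the spread between these samples.

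The deposited values are intensity per probe set on a linear scale, which the submitters' processing notes credit to MAS5. The MAS5 version, the scaling target and the array's genome build are not given in the sources used here. The table held 12488 probe sets, of which 66 were array controls. The 2% trimmed means of the 14 arrays were already nearly equal. A probe annotation gave 1 gene symbol for 10855 probe sets, several symbols for 396 and none for 1237. Gene order and chromosomes came from the GRCm38.p6 annotation, to which 10839 of the single-gene probe sets were matched by gene number. Its start coordinates served only to order genes and to bound the windows around Tnr.

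Each array was scaled to the same 2% trimmed mean, and scaled values under the 20th percentile of all values (10.1) were raised to it before log2 was taken. Probe sets at or above their array's 40th percentile on at least 3 arrays were kept, and control probe sets were left out. This left 8355 probe sets, of which 7525 had 1 gene symbol, covering 6257 genes. Values are given as mean scaled signal with SD, and differences as log2 with the SE of the model. Where most arrays of a group lay at the floor, the fold is a bound; where fewer did, the fitted value depends on the floor.

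Differences were fitted in R 4.3.3 with limma 3.58.1 (lmFit, then eBayes with a mean-variance trend), with 4 group means over all 14 arrays, 10 residual degrees of freedom and 4.97 prior degrees of freedom. Tests were two-sided, and a probe set was called at a Benjamini-Hochberg adjusted p under 0.05 over the 8355 tested. The comparisons were knockout against wild type at P7, in adults and over both ages, the difference between the ages in the knockout effect, and adult against P7 in each genotype. The number of arrays limits the precision: the median SE of a log2 difference was 0.23 at P7 and 0.27 in adults for the knockout comparisons. The procedure was tested on simulated data with the spread of each probe set on these arrays and independent noise between probe sets. Over 5 runs, 250 probe sets were changed at each of log2 0.5, 1, 2 and 3. A change of log2 1 was recovered for 52.0% of the changed probe sets at P7 and 36.8% in adults, and a change of log2 2 for 88.4% and 82.4%. The false share of calls was 4.91% and 4.94%. With that many changed probe sets the adjusted threshold is easier to pass than where few differ. The simulated noise also held no structure shared between probe sets. These rates therefore need not carry over to the knockout comparisons.

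Gene lists were tested with camera (limma, preset inter-gene correlation 0.01) on 1 probe set per gene, the one of highest mean, with adjustment over the lists. There were 21 lists: perineuronal net and hyaluronan matrix, Tnr partners at the cell surface, myelin and oligodendrocyte, oligodendrocyte precursor, astrocyte, microglia and complement, GABAergic neuron, GABA and glycine receptor, glutamatergic synapse, presynaptic vesicle, activity-regulated, immature neuron and axon growth, cell cycle, cerebellum, striatum, hypothalamus and pituitary, choroid plexus, vascular and meningeal, blood, ribosomal protein, and oxidative phosphorylation. Lists with fewer than 5 measured genes were not tested, which left 20. Some genes sit on more than 1 list.

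The groups, comparisons, tests, gene lists and the rule for named genes were fixed before the data were examined. For each knockout comparison the rule named probe sets with 1 gene symbol, past the threshold and without overlap between the groups, up to 10 in each direction by size. Where fewer passed, each direction was filled up to 5 by smallest p, and these are described as not past the threshold. For adult against P7 in wild type it named the 10 largest rises and the 10 largest falls. For the difference between ages it named the 3 of smallest p where none passed. It also named up to 4 members of each list described, 13 fixed genes of the matrix, glia and interneurons where measured, and called neighbours of Tnr. Other genes that are named were chosen after their values were seen.

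The alternatives tried were quantile normalization, scaling by the 75th percentile, a pseudocount in place of the floor, no floor, no filter, a stricter filter at the 60th percentile, no mean-variance trend, array weights, 1 probe set per gene, the mean of all probe sets of a gene, separate fits of the groups compared, replicate number as a block, camera with an estimated correlation, fry in place of camera, neighbour windows of 75 and 300 genes, and each array left out in turn. Alternatives chosen after the data were seen were a block for a pair of array sets found at P7, each of these sets alone, the fit without 2 arrays of high Xist signal, and neighbours of any gene type or past an unadjusted p. Raw image data were not used here.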

Results

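The series measured gene expression in the entire brain of mice without tenascin-R, a glycoprotein of the extracellular matrix that is enriched in perineuronal nets, at P7 and in adults. Knockout and wild type were represented by 4 arrays each at P7 and by 3 each in adults. The array had 0 probe sets annotated to Tnr, so the genotype labels were not checkable from the level of their target. The median deposited signal per array was 64.2 ± 1.60 (SD, n = 4) in wild type and 65.3 ± 2.00 (n = 4) in knockout at P7, and 84.5 ± 1.97 (n = 3) and 82.9 ± 1.25 (n = 3) in adults. The low end differed more with age, with a 20th percentile of 7.27 ± 0.54 (n = 4) and 7.64 ± 0.63 (n = 4) at P7 against 16.2 ± 1.91 (n = 3) and 14.2 ± 0.44 (n = 3) in adults.

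Age separated the arrays on the leading principal component, which held 51.4% of the variance. The next component, with 13.7%, parted the P7 arrays into 2 sets of 4 that crossed genotype: wild type 1 and 2 with knockout 1 and 3, and wild type 3 and 4 with knockout 2 and 4. Gapdh, a glycolytic enzyme measured at both ends of its transcript, had a 3′ to 5′ signal ratio of 2.25 to 3.50 on 7 of the 8 P7 arrays, 0.789 on knockout P7 array 1, and 0.768 to 0.904 on the 6 adult arrays. Xist, the RNA that coats an inactive X chromosome, had a signal of 213 on wild type P7 array 2 and of 416 on wild type adult array 1, against at most 25.1 on the other 12, although every animal is labelled male.

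**Figure D1:**
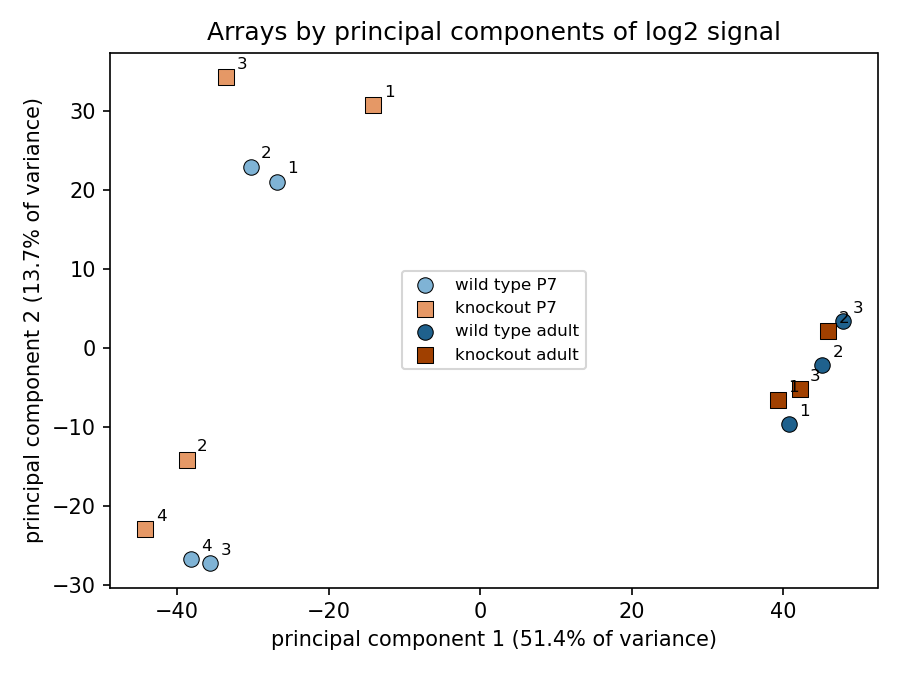
Each point is 1 array at its scores on the leading components of log2 signal (arbitrary units, share of variance in percent on each axis), with its replicate number; circles are wild type, squares knockout. Adult arrays lie to the right, and the 8 P7 arrays form 2 sets that each hold 2 arrays of either genotype.

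The comparison at P7 asked which transcripts differ in the early postnatal brain when Tnr is absent. Gas5, a growth-arrest transcript that hosts small nucleolar RNAs, was the 1 probe set called by limma. Its signal (98531_g_at, chromosome 1) was 824 ± 257 (SD, n = 4) in wild type and 105 ± 22.6 (n = 4) in knockout, a log2 difference of -2.95 ± 0.43 (SE) with adjusted p = 0.0479. All 4 knockout arrays, at 77.0 to 131, lay below all 4 wild-type arrays, at 632 to 1197. Within the array sets the log2 difference was -3.00 and -2.89 (2 arrays against 2 in each). The SE pools the spread of all 4 groups, including the knockout adult arrays. Those read 808, 131 and 725 and are not compared here. The call rested on a narrow margin. It was lost when any of the 8 P7 arrays or any of the 3 wild type adult arrays was left out (adjusted p 0.0968 to 0.228, log2 -3.06 to -2.75 over all 14 omissions) and kept without knockout adult array 1, 2 or 3. A second Gas5 probe set, 98530_at, read -1.10, with 3 of 4 knockout arrays at the floor.

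**Figure D2:**
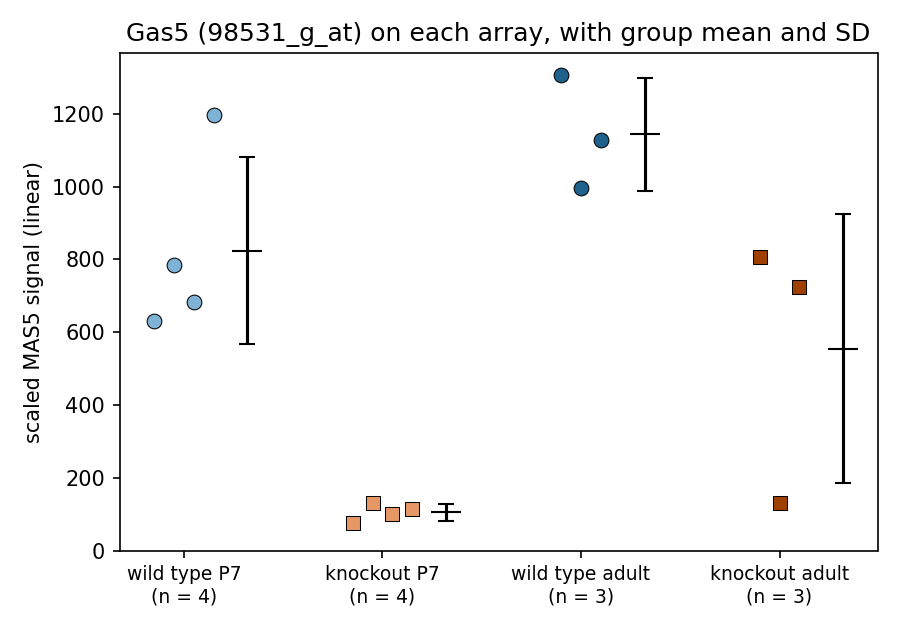
Scaled MAS5 signal (linear axis) of Gas5 probe set 98531_g_at on each array, by group, with the group mean and SD as a bar at the right of the points. The 4 knockout P7 arrays lie between 77.0 and 131 and the 4 wild type P7 arrays between 632 and 1197, while the 3 knockout adult arrays read 808, 131 and 725.

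With Gas5 counted, 507 of 8355 probe sets had an unadjusted p under 0.05, where 418 would be expected by chance, and 241 (2.88%) showed no overlap between the groups, where chance gives 2.86%. The other genes of smallest p did not pass the threshold. S100b, a calcium-binding protein of astrocytes, read 206 ± 50.3 (SD, n = 4) in wild type and was lower in knockout by a log2 difference of -1.04 ± 0.21 (limma adjusted p = 0.360). Gng11, a G protein gamma subunit, read 45.4 and 14.7 (-1.58 ± 0.30, adjusted p = 0.360, 1 of 4 knockout arrays at the floor), and Nt5dc2 read 346 and 609 (0.80 ± 0.17, adjusted p = 0.499). Gpcpd1 at -1.18 and the sialyltransferase St8sia3 at -0.61 were lower, and Rbms2 at 1.32 (1 of 4 wild type arrays at the floor), the folate enzyme Shmt1 at 1.41, the E2F partner Tfdp1 at 1.14 (others -0.19 and -0.25) and the helicase Hltf at 1.08 were higher, with adjusted p of 0.360 to 0.703. With the array set as a block, a choice made after the sets were seen, 4 probe sets were called: Gas5 at -2.95 (adjusted p = 0.0268), Gng11 at -1.58, the presynaptic scaffold gene Lin7b at -0.94 and the ubiquitin-conjugating enzyme gene Ube2h at 0.97.

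No gene list passed camera's threshold at P7, by the preset correlation, by an estimated one or by fry (0 of 20 each). The lists of smallest adjusted p were myelin and oligodendrocyte, with a median log2 difference of -0.29 over 12 genes, and immature neuron and axon growth, with 0.13 over 22 genes (adjusted p = 0.0622 for both, 0.727 with an estimated correlation). In the myelin list Mog, a surface glycoprotein of myelin, read -1.31 ± 0.45 (1 of 4 knockout arrays at the floor) and Mag -0.89 ± 0.50, and none of its 12 genes passed. In the immature neuron list the transcription factor gene Sox4 read 0.75 ± 0.23 and the surface antigen gene Cd24a 0.57 ± 0.20. Adjusted over the list alone, S100b was called in the astrocyte list and the opioid precursor gene Penk in the striatum list, both lower. The perineuronal net list had a median of 0.07, although camera ranked it lower, and the Tnr partner list a median of -0.28 (adjusted p = 0.250). Medians of the presynaptic list (-0.06) and the hypothalamus list (0.11) differed in sign from their means (0.03 and -0.03). Among genes fixed in advance, Tnc, a tenascin related to Tnr, read 0.27, the lectican Bcan 0.36, the Tnr receptor Cntn1 0.17, Mbp -0.25 (96311_at), Gad1 -0.14 and Pvalb 0.37 (96719_i_at) but -1.30 (96720_f_at, a bound with 3 of 4 knockout arrays at the floor), none past the threshold; the signs of Tnc, Cntn1 and Mbp changed under some alternatives.

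In adults the question was whether the mature brain without Tnr differs, and limma called 0 of 8355 probe sets. The smallest adjusted p was 0.793, and 198 probe sets had an unadjusted p under 0.05, where 418 would be expected. Groups without overlap numbered 743 (8.89%), where chance gives 1 in 10. Gas5 was again among those of smallest p: 98530_at read -2.43 ± 0.52, at least 5.40-fold lower with 2 of 3 knockout arrays at the floor, and 98531_g_at read -1.42 ± 0.50, with knockout arrays at 808, 131 and 725 against 996 to 1305 in wild type. Tead2, a transcription factor of the Hippo pathway, read 67.3 ± 21.9 (SD, n = 3) in wild type and 17.7 ± 7.72 (n = 3) in knockout (-1.96 ± 0.38). B2m, the light chain of class I histocompatibility molecules, read 248 ± 92.9 and 558 ± 52.1 (1.23 ± 0.33). Other genes named by the rule, at adjusted p of 0.793 to 1.00, were T2 (-1.58), Ifitm1 (-0.93) and Cdca7l (-1.07) on the lower side. On the higher side were Flt1 at 1.87 (another probe set 0.04), Gstm5 at 1.94 (others 0.03 to 0.48), Prp2 at 1.66 (another -1.18) and Polrmt at 1.11 (another -0.09). Prp2 was called when knockout adult array 1 was left out (adjusted p = 0.00352). With no filter on dim probe sets adult calls did appear, and their count is given in the closing section.

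Of the lists, blood passed camera in adult knockout brains at the preset correlation, with a median log2 difference of 0.75 over 5 genes (adjusted p = 0.00804), but not with an estimated correlation (0.408) or by fry (0.898). The other 19 lists did not pass. The haemoglobin gene Hba-a1 read 0.85 ± 0.38, the haem synthesis gene Alas2 0.77 ± 0.59, the granulocyte gene S100a8 0.75 ± 0.60, Camp 0.57 ± 0.53 and Slc4a1 0.47 ± 0.62. None of the 5 genes passed, over all genes or adjusted over the list alone. The list's adjusted p was 0.211 without wild type adult array 1. Leaving out any of 3 arrays left fewer than 5 genes, and the list was then not tested. Medians of the other lists lay between -0.11 (choroid plexus) and 0.09 (hypothalamus and pituitary), and the microglia list had 1 gene, B2m, higher when adjusted over the list alone. The GABAergic neuron and vascular lists had medians just below 0 and means above it (0.02 and 0.03), the myelin list a median just above 0 and a mean of -0.02, the activity-regulated list a median of -0.04 and a mean at 0, and the cell cycle list a median at 0 and a mean of -0.07. Tnc read -0.56, Cntn1 0.34, Gad1 0.13, Mbp -0.11 (96311_at), Pvalb -0.10 (96719_i_at) and Bcan 0.00, none past the threshold; the signs of Bcan and Gad1 changed under some alternatives.

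Over both ages, taken as the mean of the P7 and adult differences, limma called 0 probe sets, with 247 at an unadjusted p under 0.05. Gas5 (98531_g_at) came nearest at -2.18 ± 0.33 (adjusted p = 0.0678), and was called when knockout adult array 1, 2 or 3 was left out (adjusted p 0.000690 to 0.0495). Groups failed to overlap at both ages for 8 probe sets (0.0958%), where chance gives 0.143%. The rule named the heparan sulphate proteoglycan gene Sdc1 (1.12, with 2 of 4 wild type P7 arrays at the floor), Nt5dc2 (0.53), Siva1 (0.40), Maged1 (0.30) and the hyaluronidase gene Hyal2 (0.64) as higher and Rer1 (-0.19) as lower, none past the threshold. The blood list was again higher, with a median of 0.53 (camera adjusted p = 0.0345, 0.552 with an estimated correlation, 0.766 by fry). That call was lost without wild type P7 array 1, knockout P7 array 1 or wild type adult array 1 (adjusted p 0.0607 to 0.234). It was also lost with the array set as a block (camera adjusted p = 0.0776) and with array weights (0.130). The presynaptic list had a median of -0.01 and a mean of 0.06, the cell cycle list 0.01 and -0.01, and the choroid plexus list a median of -0.02 although camera ranked it higher. Across the 8355 probe sets the P7 and adult knockout differences had a Pearson r of -0.03 and a Spearman rho of -0.07, and 47.0% shared a sign. Of 100 splits of the labels 79.0% gave an r as far from 0, with probe sets not being independent replicates.

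A test of the difference between the ages in the knockout effect called 0 probe sets by limma, with 324 at an unadjusted p under 0.05. The 3 of smallest p were the glutathione transferase gene Gstm5 (3.04 ± 0.65), B2m (2.00 ± 0.44) and Tead2 (-2.20 ± 0.51), all at adjusted p = 0.991. Gstm5 was called without wild type P7 array 1 (adjusted p = 0.0210). The immature neuron list differed between the ages, with a median of -0.35 over 22 genes (camera adjusted p = 0.0395, 0.571 with an estimated correlation, 0.625 by fry). Sox4 differed by -0.65, Cd24a by -0.57 and the intermediate filament gene Nes by -0.70, while Dpysl3 went the other way at 1.03. The call was lost without wild type P7 array 1, knockout P7 arrays 2 or 4, wild type adult arrays 2 or 3, or knockout adult array 1 (adjusted p 0.0861 to 0.183). Ribosomal protein genes had a median of 0.06 and a mean of -0.03, and the GABAergic list a median of 0.11 and a mean just below 0.

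Counted by the starts of protein-coding genes, Gas5 lies at position 11 after Tnr on chromosome 1. Its neighbourhood was tested in a fit of 1 probe set per gene, adjusted over 6257 genes, in which Gas5 was the 1 gene called over both ages. Of 91 tested genes within 150 protein-coding genes of Tnr on either side 0 were called, against 1 of 6166 others (Fisher's exact test, two-sided, p = 1.00). That gene was Gas5, counted among the others because it is not protein-coding. At an unadjusted p under 0.05, a choice made after the data were seen, 7 of the 91 (7.69%) and 185 of 6166 (3.00%) passed over both ages (Fisher's exact p = 0.0212). At P7 alone these were 8 (8.79%) and 388 (6.29%; Fisher's exact p = 0.283), and in adults 5 (5.49%) and 137 (2.22%; Fisher's exact p = 0.0552). With genes of any type counted and Gas5 left out, 7 of 93 (7.53%) and 184 of 6163 (2.99%) passed over both ages (Fisher's exact p = 0.0230). That excess was reached by 7 of 100 splits of the labels, the real one included, drawn without regard to the P7 array sets. Of these 7 neighbours, 5 were lower in knockout. The larger falls were those of the sulfhydryl oxidase gene Qsox1 at -1.10 ± 0.28 and the torsin gene Tor3a at -0.70 ± 0.22, which lie 22 and 12 genes before Tnr. The Qsox1 value is that of 1 probe set, and its other probe set is not described here. Cop1, 1 gene before Tnr, went the other way at 0.61 ± 0.26, as did Cyb5r1 at 0.28 ± 0.11.

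Between P7 and adulthood the wild-type brain changed far more. Limma called 2621 of 8355 probe sets, 1568 higher (1266 genes) and 1053 lower (904 genes). The median of all probe sets was shifted by 0.17, so changes below are relative to it. Limma's calls, adjusted p and counts of genes higher or lower come from the unshifted differences. Some called rises are therefore small on the relative scale, such as Plk1 at 0.29 ± 0.17 and Gad1 at 0.28 ± 0.15. Of the calls 59.8% were rises as scaled, 52.4% under scaling by the 75th percentile and 44.6% under quantile normalization. Mobp, a myelin protein gene, rose by 4.88 ± 0.79 and 3.98 ± 0.43 on the probe sets of largest rise and read 2.67 and 2.61 on its other 2. The G protein regulator gene Rgs4 rose by at least 4.17, the Purkinje cell gene Ppp1r17 by at least 4.06 (another probe set 2.19), the synaptic kinase gene Camk2a by at least 3.82 on 93659_at, and the AMPA receptor gene Gria3 by at least 3.63. With part of the P7 arrays at the floor, the vesicle protein gene Vamp1 rose by 4.13 ± 0.89 (another probe set 1.99), muscle-type glycogen phosphorylase Pygm by 3.80 ± 0.58 and Camk2a by 3.78 ± 0.56 on 93660_at, values that depend on the floor. Csrp1, a LIM domain gene, rose by 3.64 ± 0.35 (another probe set 2.86). Fabp7, a fatty acid binding protein of radial glia, fell from 3334 (n = 4) to 339 (n = 3), a relative change of -3.51 ± 0.24, and the migrating-neuron gene Dcx from 974 to 110 (-3.24 ± 0.33). Other large falls were Kcne1l (-3.97), Mapk7 (-3.59), the mitotic kinase gene Cdk1 (-3.57, a bound), Bzw2 (-3.39), Cks1b (-3.30, with 1 of 3 adult arrays at the floor), the interneuron transcription factor gene Dlx2 (-3.25), Traf4 (-3.81 on 162482_at, -0.87 on another probe set) and Sipa1 (-3.66 on 97963_at, a bound, but 2.05 on another probe set).

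Lists of synaptic and myelin genes rose with age in wild type. The myelin list had a relative median of 1.14, with 8 of 12 genes higher and 0 lower (10 adjusted over the list alone), among them Mal (2.14), Mog (1.77) and Mbp (1.52 on 96311_at, but -0.28 and not past the threshold on 96310_at); its camera adjusted p was 0.000143, and 0.157 with an estimated correlation. The glutamatergic synapse list rose by 0.81 (12 of 20 higher, 12 adjusted over the list alone; 0.000410, estimated 0.121), led by Gria3 and Camk2a. The presynaptic vesicle list rose by 0.94 (6 of 15, 7 adjusted over the list alone; 0.00228, estimated 0.0971), with Snap25 at 1.55 and Cplx1 at 2.81. GABA and glycine receptors rose by 0.71 (6 of 14 higher and 1 lower, 8 and 2 adjusted over the list alone; 0.0208, estimated 0.251), with Gabra6, a subunit of cerebellar granule cells, at 3.30. The cerebellum list rose by 0.52 (7 higher and 1 lower of 14, alike adjusted over the list alone; 0.0121, estimated 0.345) and the striatum list by 0.52 (3 of 5, alike over the list alone; 0.0208, estimated 0.121). The immature neuron list fell, with a relative median of -1.27 and 15 of 22 genes called lower (15 adjusted over the list alone, camera adjusted p = 1.38e-08, estimated 0.00954). Among those called were Cd24a (-3.17), Marcksl1 (-2.79) and Sox11 (-2.03). Cell cycle genes fell by 0.84 (7 of 21 lower and 1 higher, 8 and 1 adjusted over the list alone; 0.00352, estimated 0.343), with Ccnd2 at -2.91 and Top2a at -1.91 (a bound). Ribosomal protein genes fell by 0.57 (7 of 25 lower and 1 higher, 7 and 2 adjusted over the list alone; 0.0123, estimated 0.345), with Rplp0 at -1.63; this call was lost under quantile normalization (0.295), with the mean of all probe sets of a gene (0.136) and with no filter (0.0809). The calls on GABA and glycine receptors and striatum were lost with no filter (0.0809 for both), the former with a stricter filter (0.0877) and the latter with array weights (0.0543). Of the 20 lists, fry called 13.

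The other tested lists did not pass camera in wild type. The perineuronal net list had a relative median of -0.30, with the lectican gene Vcan at -1.41 and the phosphatase gene Ptprz1 at -1.75 (92379_f_at) lower and the sulfotransferase gene Chst3 at 1.68 (1 of 4 P7 arrays at the floor) higher (5 lower and 2 higher of 17). Other Ptprz1 probe sets read -0.84 (called) and -0.97 (not called). Tnc fell by 1.07 and Ncan (98798_at) by 0.77. Another Ncan probe set, 98799_g_at, read -1.66 with some arrays at the floor. Tnc's call was lost without wild type P7 arrays 3 or 4, any of the 3 wild type adult arrays or knockout adult array 1 (adjusted p 0.0501 to 0.120), and that of Ncan 98798_at without wild type adult array 2 (0.0657). Among Tnr partners the axonal channels Kcna2 (3.43, with 1 of 4 P7 arrays at the floor) and Kcna1 (2.07) rose while Ncam1 (-1.73) and Chl1 (-1.76) fell (5 higher and 4 lower of 14, median 0.25). The GABAergic list (0.16) held 7 higher, such as Pvalb (1.25) and Vip (at least 2.06), and 3 lower, such as Dlx1 (-3.09). Relative medians were 0.31 for astrocyte (6 higher, 1 lower), 0.28 for microglia (4 higher), 0.21 for activity-regulated (5 higher, 2 lower), 0.57 for hypothalamus and pituitary (5 higher), 0.19 for choroid plexus (3 higher, 2 lower), -0.24 for vascular (5 higher, 7 lower), 0.19 for blood (1 higher) and -0.11 for oxidative phosphorylation (10 higher, 7 lower), whose unshifted mean was 0.09. The oligodendrocyte precursor list, with 4 measured genes, was not tested. On it Pdgfra fell by 0.81 (1 of its 2 probe sets) and Ptprz1 by 1.75 (others -0.84 and -0.97). Acan and Hapln1 were on the array but too dim to test, and Scn2b had no probe set.

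In knockout brains the same comparison called 2284 probe sets, 1349 higher (1084 genes) and 935 lower (807 genes), with a median shift of 0.12. Of the calls 59.1% were rises as scaled and 46.2% under quantile normalization. Both genotypes shared 1680 called probe sets, of which 1679 moved in the same direction, while 941 were called in wild type alone and 604 in knockout alone; the age differences of the genotypes had an r of 0.86 across probe sets. None of these differences between genotypes was called when tested. Camera called 12 lists in knockout, the 9 of wild type plus astrocyte (0.62), microglia (0.65) and hypothalamus (0.86). The ribosomal call was lost under quantile normalization (0.169) and with the mean of all probe sets of a gene (0.0590), and the astrocyte call with no filter (0.0610). With an estimated correlation only the immature neuron (0.00331) and presynaptic (0.0485) lists passed. The perineuronal net list had a relative median of 0.22 and the choroid plexus list of 0.01 although camera ranked both lower, and oxidative phosphorylation -0.05 although ranked higher. Mbp rose by 1.70 on 96311_at but read -0.22 on 96310_at, which did not pass, and Tnc fell by 1.85 in knockout, each relative to the shift. Likewise relative, Gfap in knockout read -0.72 on 94144_g_at but 0.15 on 94143_at, which did not pass. The limma adjusted p of 94144_g_at, 0.0142, is that of the unshifted difference. In wild type these Gfap probe sets read -0.55 and 0.40, neither past the threshold. Nrcam read 0.16 in knockout and 0.12 in wild type, neither past the threshold. Age was also the line along which the low end of the signal and the Gapdh ratio differed, so the age comparisons carry any difference in array handling between the ages.

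**Figure D3:**
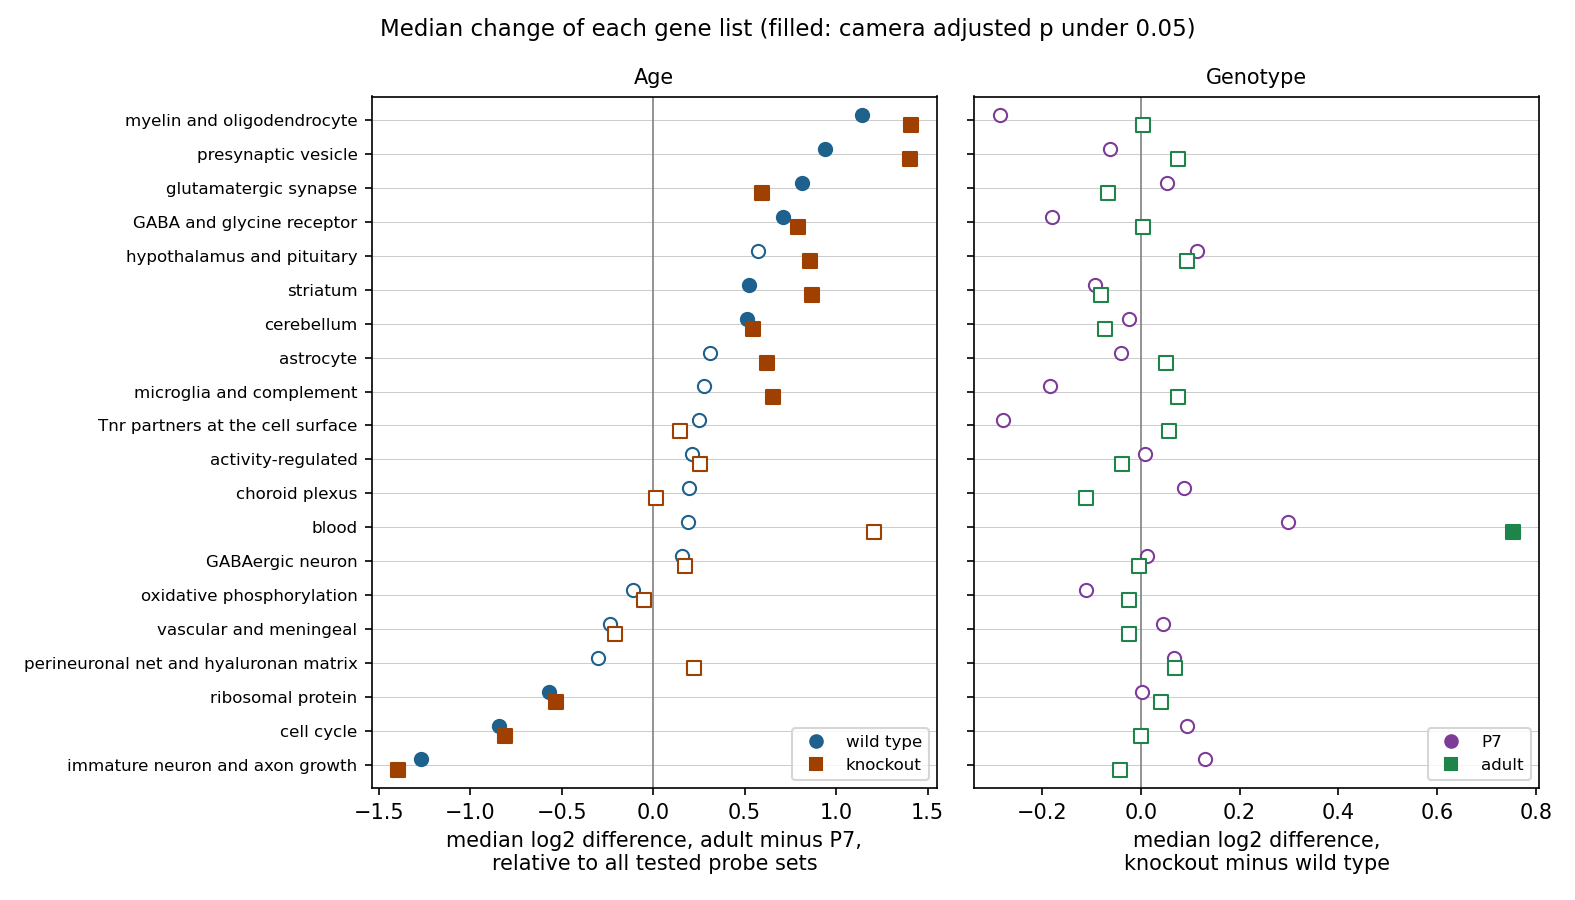
Median log2 difference of each gene list (1 probe set per gene), with age on the left panel relative to all probe sets and genotype on the right panel; filled symbols passed camera at the preset correlation. Age medians run from -1.27 (immature neuron) to 1.14 (myelin) in wild type, and of the P7 and adult genotype medians drawn, 1 is filled, blood in adults at 0.75.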

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

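The tests on Gas5, on the P7 array sets and on Xist were chosen only after the results were seen; the counts of splits were planned, with their reading written down afterwards. Single arrays that stood apart from the others of their group are given first; 8 of 129 groups of 4 arrays did so (6.20%), and chance gives about 1 in 20. Knockout P7 array 4 read 269 for St8sia3 (others 197 to 206) and 144 for Tnc (91.9 to 98.5). Wild type P7 array 4 had a deposited median of 61.8 (64.7 to 65.3). Knockout P7 array 1 read 9307 at the 5′ end of Gapdh (1454 to 1781). Wild type P7 array 2 read 213 for Xist (1.98 to 3.76) and 1.25 for Eif2s3y (90.2 to 107). The myelin list had a median signal of 441 on wild type P7 array 1 (243 to 256), and the activity-regulated list 129 on knockout P7 array 3 (104 to 107). The immature neuron list was singled out because the knockout effect differed between the ages, at -0.35. No explanation was tested for the single values of St8sia3, Tnc, Gapdh and the list medians.

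Gas5 was lower in knockout brains at P7, and its gene is close to the targeted gene. Unequal sex and the array sets are argued against: the log2 difference was -2.95 without the 2 arrays of high Xist signal (adjusted p = 0.211 with fewer arrays, SE 0.50 against 0.43), and the smaller of the 2 differences within an array set was -2.89. A candidate explanation is DNA of the donor strain that stayed beside the targeted allele. Without Gas5, 7 of 93 neighbours (7.53%) and 184 of 6163 genes elsewhere (2.99%) passed an unadjusted p under 0.05. Fisher's exact test, two-sided, gave p = 0.0230. Of 100 splits of the labels 7, the real one included, gave an excess as large as 4.54 percentage points (highest other 6.69). Those splits were drawn without regard to the P7 array sets, over which the real labels are balanced, so they are not a like reference. Protein-coding neighbours at P7 alone gave Fisher's exact p = 0.283. These tests therefore do not tell the donor-strain explanation apart from chance. An effect of Tnr loss on Gas5 stays open. In adults the brighter probe set, 98531_g_at, was unevenly lower. It read 808, 131 and 725 on knockout arrays 1, 2 and 3, against 996 to 1305 in wild type. The dimmer 98530_at read at most 11.5 on every knockout adult array, near the floor, against 41.6 to 74.3 in wild type. No cause was tested against this unevenness.

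The 8 P7 arrays formed 2 sets that each held both genotypes, with correlations of 0.921 to 0.973 within a set and 0.895 to 0.931 between sets. Array scaling is argued against, since 8 of 8 arrays fell in the same set after quantile normalization. RNA integrity may differ between the sets: the actin 3′ to 5′ ratio averaged 1.22 and 1.49 (exact permutation p = 0.2, two-sided) and the same test on the Gapdh ratio gave 0.514 (smallest possible 0.0286), which leaves it open with 4 arrays in each. Stage of development also stays open, as the set difference in one genotype and the age difference in the other had correlations across probe sets of -0.0518 and -0.23. In a fit of the 8 P7 arrays with genotype held fixed, 800 probe sets were higher and 718 lower between the sets, counts raised by choosing the sets on the same values; litters, days and batches are not named in the labels.

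Xist was high and Eif2s3y, a Y-linked gene, was low on wild type P7 array 2 and wild type adult array 1. RNA of a female mixed into that of a male is argued against, since the higher Eif2s3y signal of these arrays was 2.65% of the lowest on the other 12. Female animals under a male label are consistent with Kdm6a, an X-linked gene that escapes inactivation, which was highest of its age on both arrays (143 against 71.2 to 128, and 168 against 83.2 to 107; exact p = 0.0208, one-sided). Eif2s3x, another such gene, was highest in adults (1231 against 699 to 901) but not at P7 (1144 against 790 to 1319). No other cause was tested.

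Splits of the same arrays into groups of the same sizes were counted for each comparison. At P7 the real split called 1 probe set and 9 of 35 splits, the real one included, called as many, so chance is not excluded for this count. The highest other, 1780 in the fit of all 14 arrays, was the split by array set, which points to a structure of the samples. The real split is balanced over the array sets, whereas other splits need not be. The count also disregards which probe set is called, so it does not test the Gas5 difference itself. With the array set as a block, the call of Gas5 is at -2.95. The splits over both ages and for the difference between ages likewise disregarded the array sets. Every split reaches a real count of 0, so nothing about chance follows for P7 lists (35 of 35 splits, highest other 6), probe sets over both ages (100 of 100, highest other 687) or probe sets for the difference between ages (100 of 100, highest other 342). The cause of the counts of 687 and 342 was not tested. In adults the 10 splits are too few for a share under 0.05: the real 0 probe sets were reached by all 10 (highest other 1) and the real 1 list by 5 (highest other 4). Chance is not excluded for the 1 list over both ages, reached by 68 of 100 splits (highest other 5), or the 1 list for the difference between ages, reached by 67 of 100 (highest other 9). For the probe sets that changed with age only the real split, 1 of 35, reached its count: 2621 in wild type (highest other 963) and 2284 in knockout (1363). That is the smallest share 35 splits can give, so chance is made unlikely but not excluded. For the number of lists that moved with age, 6 of 35 splits reached 9 in wild type (highest other 11). In knockout 3 of 35 splits reached 12 (highest other 12). Every other split shares the adult arrays unevenly between its groups and so carries part of the age difference. These list counts therefore settle nothing about chance.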

How the results depend on the processing

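The tests with array sets, without the 2 arrays of high Xist signal, and with neighbours of any type or past an unadjusted p were chosen only after the results were seen. No called value of a named gene or list changed sign under any alternative. For named genes, 2463 values kept their sign and side of the threshold, 23 gained and 52 lost the threshold, and 46 changed sign. These 46 belong to 16 differences, none past the threshold, such as Nrcam, Ptprz1, Cntn1 and Tnc at P7 and Bcan in adults. For the called lists, 591 medians kept their call and 50 lost it. Gas5 at P7 kept its sign in all 29 alternatives and passed in 12 (adjusted p 1.29e-05 to 0.252). The P7 count of 1 probe set became 0 under quantile normalization, with no floor, with no filter on dim probe sets, with no mean-variance trend, with array weights and without the 2 arrays of high Xist signal. It became 4 with the array set as a block, 232 in P7 array set 1 alone and 93 in P7 array set 2 alone. Within a set 2 arrays face 2, the spread was estimated over all arrays, and the sets were chosen on the same values. The reason for the higher counts was not tested. With no filter on dim probe sets, 63 probe sets were called in adults, 17 over both ages and 17 for the difference between ages. A stricter filter, 1 probe set per gene and the replicate block each gave 1 probe set over both ages, and array weights 1 for the difference between ages. Replicate numbers are not shown to pair the arrays: correlations of their residuals ran from -0.35 to 0.37. In the replicate block Gas5 had adjusted p of 0.0303 at P7 and 0.0401 over both ages. List calls at P7 went from 0 to 1 with the stricter filter and without the 2 arrays of high Xist signal, and to 2 with the replicate block and with the mean of all probe sets of a gene. The 1 adult list call became 0 with no filter, the stricter filter, an estimated correlation, fry and without the 2 arrays of high Xist signal. The 1 over both ages became 0 with the stricter filter, array weights, an estimated correlation, fry and the array set as a block, 2 with the replicate block and 3 without the 2 arrays of high Xist signal. The 1 for the difference between ages became 0 with no filter, array weights, an estimated correlation and fry. With an estimated correlation 1 list passed for age in wild type and 2 in knockout. Called neighbours of Tnr went from 0 to 1 with neighbours of any biotype, which adds Gas5, and to 7 past unadjusted p. Leaving out each array in turn gave 0 to 1 probe sets at P7 (0 without any P7 or wild type adult array), 0 to 1 in adults (1 without knockout adult array 1, wild type adult array 2 or 3), 0 to 2 over both ages (1 or 2 without a knockout adult array) and 0 to 1 for the difference between ages (1 without wild type P7 array 1 or wild type adult array 3). For lists it gave 0 to 2 at P7 (1 without wild type P7 array 2, 2 without wild type P7 array 3 or 4 or knockout P7 array 1) and 0 to 1 in adults (0 without wild type adult array 1, knockout P7 array 4 or knockout adult array 1). Over both ages it gave 0 to 2 (2 without wild type P7 array 2, 3 or 4, and 0 without wild type P7 array 1, knockout P7 array 4, wild type adult array 1 or knockout adult array 1 or 2). For the difference between ages it gave 0 to 3 (3 without knockout P7 array 1, 2 without knockout P7 array 3, and 0 without the 6 arrays named in the report). With the stricter filter and without some of these arrays the blood list had fewer than 5 genes and gave no value. A count of 0 in those settings is therefore not a lost call of the blood list. The correlation of the P7 and adult effects ran from -0.0692 to 0.0202, positive without wild type adult array 3. Apart from these constructions the cause was not tested. Signal over background limits the dim genes: 1.66% and 1.71% of tested values lay at the floor in wild type and knockout at P7, against 0.411% and 0.359% in adults.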
